A study of Drosophila melanogaster with 36 samples.

How the data were processed

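Total RNA of whole adult flies was sequenced in 36 libraries: 3 genotypes, 2 sexes and 2 doses of auxin in the food, with 3 libraries in each of 12 groups. Libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols, which name no strand-specific step, so genes that overlap on opposite strands may share reads. Per the labels' protocols, the 0 mM food listed 1 mM NaOH and the 10 mM food listed auxin and no NaOH. TopHat, HTSeq and DESeq2 were used, per the submitters' processing notes, which give no versions, order or parameters. The authors deposited a table of raw read counts per gene, with 17558 genes and no normalization. The genome build of the alignment was not given in the sources used here. Of the gene identifiers, 17252 were found in the BDGP6 annotation of Ensembl release 115, and 16959 had the same chromosome, start and end, so coordinates are given on BDGP6. In 1204 genes all counts were 0. Reads shared by near-identical gene copies could not be assigned from a table of counts, so values of single copies are reported as uncertain.

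Total counts per library were 15249093 to 19771820 in females and 16954902 to 26137040 in males. Genes were kept by filterByExpr with a minimum count of 10, within each sex, which left 10746 genes in females, 13630 in males and 13979 in the fit of both sexes. Library sizes were scaled by TMM. A fold change is therefore relative to the median gene, and not to an amount of RNA per fly, since no spike-in was present.

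Each sex was fitted with edgeR 4.0.16 (quasi-likelihood, 6 groups of 3 libraries) in R 4.3.3. The contrasts were 10 mM against 0 mM in each genotype, the mean of these 3 effects, the difference of effects among genotypes (2 degrees of freedom) and the effect in AID minus the mean effect in the other genotypes. A fit of all 36 libraries gave the difference of the mean effect between females and males. P-values were adjusted by Benjamini and Hochberg's method over the genes of each contrast, and genes with an adjusted p under 0.05 were called. Standard errors (SE) of log2 fold changes are those of the model. CPM values were computed from TMM-scaled library sizes, and their SD is over 3 libraries; for genes that check the labels, unscaled totals were used. Each genotype and sex had its own 0 mM libraries, so no comparison of genotypes shared a control library. The female 0 mM replicate 1 libraries still deviated alike in the 3 genotypes (correlations of 0.35 to 0.43), so these controls were not fully independent.

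Before the data were examined, 32 lists of genes of pathways, tissues and responses were written from general knowledge of the fly, and 5 members matched no gene of the table. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, and again with the correlation estimated for each list. P-values were adjusted over the lists of a contrast. The direction and size of a list are given as the median log2 fold change of its measured members, with the number of members called.

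Genes to be named were also chosen by a rule written before the data were examined. In each sex these were the 8 largest rises and 8 largest falls of the mean effect, among called genes with the same sign in all genotypes and an average log2 CPM of at least 2, and up to 3 members of each list by smallest p. To these were added the 3 rises and 3 falls of smallest p in each single effect, the 5 genes of smallest p in each difference, and genes that check the labels. The exception, mt:lrRNA, was chosen after its values were seen. For a group with 0 counts the fold is given as a bound, with 3 counts over the group in place of 0.

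The scripts were tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. For the mean effect, the test recovered 81% and 95% of them in females (10612 genes, 4.35% of calls false) and 91% and 100% in males (13534 genes, 3.05% false). For single genotypes it recovered 41% to 54% of 1.5-fold and 75% to 82% of 2-fold changes in females, and 73% to 77% and 90% to 92% in males. For the sex difference (13885 genes) it recovered 59% and 70%. With the list test, 0 lists were called falsely in females and 1 in males. The simulated genes were drawn independently of each other, so this does not cover lists of correlated genes. Few genes were changed, as many up as down, and libraries were drawn independently too. The recovered and false shares therefore do not carry over to the real female mean effect, where 71.0% of genes were called. With dose labels of the real libraries exchanged within genotypes, a median of 12 lists in females and 8 in males was called in the splits other than the real one. No such split balances the doses of a genotype, so each holds part of the auxin effect and these medians are not a chance rate.

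Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, no low-count filter, a filter at an average log2 CPM of 2, a block for replicate numbers, the omission of each library in turn, fits of 6 or of all 36 libraries, camera with an estimated correlation and the rotation test fry. Added after the data were seen were the omission of the 3 female 0 mM replicate 1 libraries and a scaling of libraries to the neuron and photoreceptor lists. No library was left out of the main fits.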

Results

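Whole-body transcriptomes of adult Drosophila melanogaster were measured by RNA sequencing after feeding on food with 0 mM or 10 mM auxin, a plant hormone used to trigger degradation of degron-tagged proteins. The 36 libraries fell into 12 groups of 3, made of 3 genotypes, 2 sexes and 2 doses. Oregon-R is a wild-type strain, VK00040 is a yellow white stock with an insertion site over the TM6B balancer, and AID is a white stock that carries the plant auxin receptor TIR1 and an auxin-degradable Gal80 under a tubulin promoter. Each sample held 20 flies that had been starved for 16 h and then fed for 48 h, and the 0 mM food held 1 mM NaOH, which the labels do not list for the 10 mM food. The sample labels give an age of 2 to 4 days, and the series text gives 4 to 5 days. Total counts per library ranged from 15249093 to 26137040. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

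Transcripts that differ by sex followed the labels in every library. Yp1, which encodes a yolk protein, ranged from 2386 to 4458 CPM (counts scaled to a library total of 1e6) in female libraries and from 0.055 to 1.25 CPM in male libraries. The dosage compensation RNA roX1 ranged from 597 to 790 CPM in males and from 1.18 to 14.0 CPM in females. The eye pigment transporter gene w was lowest in VK00040, at 0.12 to 0.64 CPM in females and 2.06 to 3.66 CPM in males. In AID it reached 4.75 to 7.08 CPM in females and 24.7 to 37.6 CPM in males, against 8.23 to 16.9 and 12.3 to 24.3 CPM in Oregon-R. The AID males thus lay above the Oregon-R males, which was not explained.

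In each of the 3 genotypes, replicate 1 of the female 0 mM group stood apart from replicates 2 and 3. The mitochondrial large ribosomal RNA mt:lrRNA took 7.30% to 9.60% of the counts in these 3 libraries, against 2.16% to 3.64% in the other 6 female 0 mM libraries and 2.72% to 3.82% in the 9 female 10 mM libraries. Cytoplasmic ribosomal protein genes took 6.88% to 8.12% of their counts, against 8.52% to 10.1% in the other 6. In males, mt:lrRNA moved with the dose: its mean share was 2.80% ± 0.44 (SD, n = 3) at 0 mM and 4.98% ± 0.67 (SD, n = 3) at 10 mM in Oregon-R. In VK00040 males the shares were 5.36% ± 0.18 and 6.83% ± 0.59, and in AID males 6.40% ± 0.38 and 7.19% ± 0.59 (SD, n = 3 each).

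**Figure D1:**
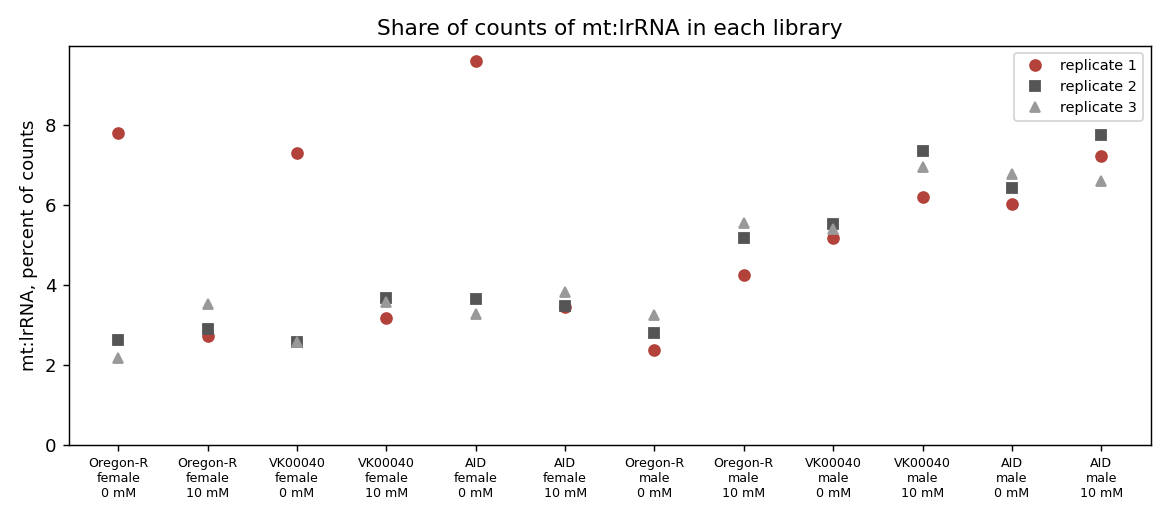
Share of counts of mt:lrRNA (percent, vertical axis) in each of the 36 libraries, by group, with the symbol giving the replicate number. Replicate 1 of the 3 female 0 mM groups lies at 7.30% to 9.60%, and replicates 2 and 3 of these groups lie at 2.16% to 3.64%.

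The first question was which transcripts respond to auxin feeding in each genotype and sex. In females, 4779 of 10746 genes changed in Oregon-R (2623 higher and 2156 lower), 5884 in VK00040 (3008 and 2876) and 4723 in AID (2610 and 2113), by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Of these, 1886 genes rose and 1449 fell in all 3 genotypes, where independent lists would share 178 and 113. That expectation takes libraries of different genotypes as independent, which the female 0 mM replicate 1 libraries were not. The mean effect over genotypes called 7632 genes, 3814 higher and 3818 lower, and 1330 of the rises and 355 of the falls were at least 2-fold. Across genes, which are not independent replicates, fold changes of pairs of genotypes correlated with Pearson's r of 0.64 to 0.75 (0.32 to 0.39 with no low-count filter, 0.42 to 0.48 in 1 fit of all 36 libraries). Without the 3 female 0 mM replicate 1 libraries, a setting chosen after the data were seen, r was 0.62 to 0.68 and the mean effect called 8192 genes. Of the 7632 genes, 7203 were called there too, all in the same direction.

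**Figure D2:**
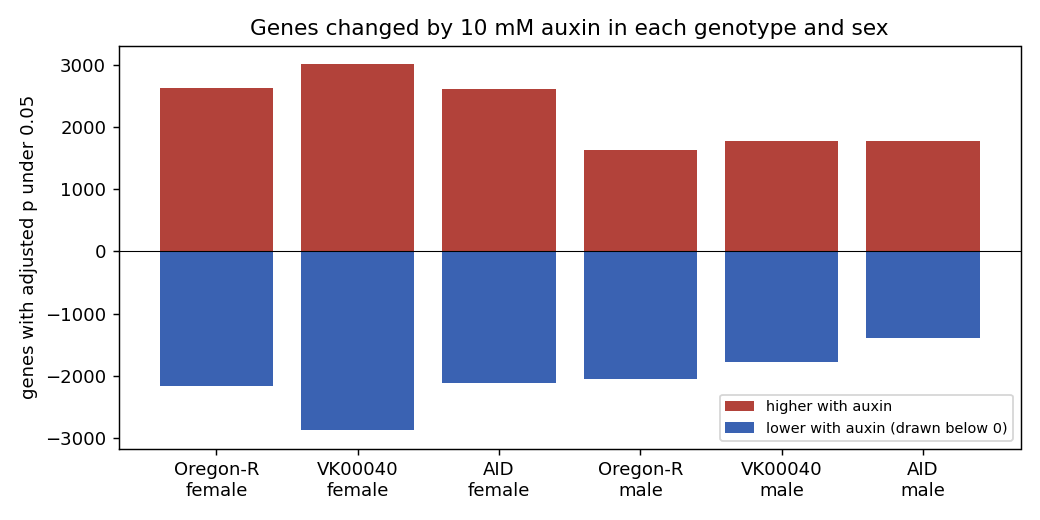
Number of genes with an adjusted p under 0.05 for 10 mM against 0 mM auxin in each genotype and sex (vertical axis, genes), with genes higher with auxin above 0 and genes lower with auxin below 0. The counts run from 3157 genes in AID males to 5884 in VK00040 females.

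The female rises of largest size were in a cytochrome P450 gene and several genes with few annotated functions. Cyp6a21 (FBgn0033981; 2R, 14885264 to 14886947, minus strand, BDGP6) went from 10.9 ± 2.0 to 372 ± 45 CPM in Oregon-R, from 6.67 ± 2.43 to 528 ± 77 CPM in VK00040 and from 10.3 ± 3.0 to 482 ± 23 CPM in AID (SD, n = 3 each). Its mean log2 fold change was 5.65 (SE 0.14, edgeR adjusted p 1.2e-14). CG34217 rose by 5.28 (SE 0.21), CG13905 by 4.84 (SE 0.13), CG31272 by 3.64 (SE 0.13), CG14219 by 3.36 (SE 0.37) and CG10182 by 3.28 (SE 0.24). CG9498 (FBgn0031801; 2L, 6349393 to 6351034, minus strand) rose by 3.42 (SE 0.06), from 24.6 to 30.8 CPM at 0 mM to 219 to 374 CPM at 10 mM over the genotype means. Gnmt, the glycine N-methyltransferase gene, rose by 3.64 (SE 0.16). Its log2 fold change was 1.74 in Oregon-R, 4.56 in VK00040 and 4.63 in AID.

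Genes of detoxification and export rose widely in females. Of 78 cytochrome P450 genes, 54 rose and 7 fell, with a median log2 fold change of 0.66 (camera adjusted p 2.5e-06 with a preset correlation, adjusted p = 0.20 with an estimated correlation; median -0.31 when libraries were scaled to the neuron and photoreceptor lists). Cyp6a9 rose by 2.52 (SE 0.10) and Cyp4g1, which acts in cuticular hydrocarbon synthesis, by 1.42 (SE 0.06). Among 34 glutathione transferase genes 18 rose and 9 fell, with a median of 0.31 (adjusted p 0.0039, adjusted p = 0.20 with an estimated correlation; median -0.67 under the neural scaling). GstD7 rose by 3.00 (SE 0.13), GstE3 by 2.43 (SE 0.10) and GstO3 by 1.94 (SE 0.07). Of 34 UDP-glycosyltransferase genes 23 rose and 4 fell, with a median of 0.72 (adjusted p 0.00041, adjusted p = 0.29 with an estimated correlation; median -0.24 under the neural scaling). Among 13 ABC and organic anion transporter genes 12 rose and none fell, with a median of 0.68 (adjusted p 8.3e-08, adjusted p = 0.086 with an estimated correlation; median -0.29 under the neural scaling). Mdr50, a P-glycoprotein gene, rose by 2.60 (SE 0.10), and the organic anion transporter gene Oatp58Dc by 2.22 (SE 0.08). Adjusted over the list alone, the counts of these 4 lists were the same.

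Lipid synthesis and amino acid breakdown moved the same way in females. Of 29 fatty acid synthesis genes 27 rose and 2 fell, with a median of 0.78 (camera adjusted p 2.3e-10, adjusted p = 0.087 with an estimated correlation; median -0.19 under the neural scaling), and the counts were the same when adjusted over the list alone. CG33110 rose by 1.84 (SE 0.07) and CG16904 by 1.17 (SE 0.06). CG1942 (Dgat2), a diacylglycerol acyltransferase gene, rose by 3.24 (SE 0.16), whereas the triglyceride storage and lipolysis list as a whole split into 6 rises and 11 falls of 30 (adjusted p 0.078). Of 28 amino acid catabolism genes 23 rose and 1 fell, also when adjusted over the list alone (median 0.49, adjusted p 9.7e-05, adjusted p = 0.20 with an estimated correlation; median -0.49 under the neural scaling). Uro, the urate oxidase gene of the Malpighian tubule, rose by 2.13 (SE 0.08). Among 20 lipoprotein and lipid transport genes 14 rose and 4 fell, also when adjusted over the list alone (median 0.66, adjusted p 0.00033, adjusted p = 0.19 with an estimated correlation; median -0.30 under the neural scaling). Npc2b, a sterol-binding protein gene, rose by 1.55 (SE 0.09).

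Digestive protease genes fell in females. Of 47 measured, 33 fell and 9 rose, also when adjusted over the list alone, with a median of -0.84 (camera adjusted p 4.9e-09, adjusted p = 0.20 with an estimated correlation). Jon99Ci, a serine protease of the Jonah family (FBgn0003358; 3R, 29925226 to 29926189, minus strand), went from 194 ± 17 to 23.5 ± 0.9 CPM in Oregon-R, from 279 ± 42 to 120 ± 11 CPM in VK00040 and from 323 ± 32 to 16.8 ± 3.9 CPM in AID (SD, n = 3 each). Ser8 fell by 3.24 (SE 0.12) and CG12374 fell by 3.12 (SE 0.11) on the log2 scale. CG17192, a predicted lipase gene, fell by 7.04 (SE 0.20) as a mean over genotypes, and its mean in AID went from 113 ± 23 to 0.072 ± 0.036 CPM (SD, n = 3 each). Jon25Bi and Jon25Bii fell by 5.61 (SE 0.24) and 5.55 (SE 0.30), but these 2 genes are near-identical, so their separate values are uncertain. The same holds for PGRP-SC1a and PGRP-SC1b, amidase genes of the gut, which fell by 5.13 (SE 0.29) and 3.74 (SE 0.29). TwdlF, a cuticle protein gene, had 287 counts over the 3 Oregon-R libraries at 0 mM and 0 at 10 mM, which is at least 104-fold lower against a floor of 3 counts over the group. Digestive carbohydrase genes went both ways, with 10 rises and 8 falls of 21, a median of 0.32 and a mean of -0.22 (adjusted p 0.89). By genotype, 13 rose and 2 fell in VK00040 (median 1.12, adjusted p 0.00075, adjusted p = 0.33 with an estimated correlation), 2 rose and 5 fell in Oregon-R (median -0.11, adjusted p 0.32) and 6 rose and 7 fell in AID (median 0.08, mean -1.19, adjusted p 0.10). The rise of Mal-B1 was 2.38 (SE 0.15).

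Ovarian transcripts fell in females while markers of 5 other tissues rose and those of the fat body did not rise as a list. Of 26 eggshell genes, expressed in the follicle cells of the ovary, 25 fell and none rose, also when adjusted over the list alone (median -1.37, camera adjusted p 4.9e-09, adjusted p = 0.19 with an estimated correlation). Cp18, a chorion protein gene, fell by 2.00 (SE 0.16). Of 33 ovarian germline genes 28 fell and 2 rose, or 3 adjusted over the list alone (median -0.39, adjusted p 2.7e-06, adjusted p = 0.19 with an estimated correlation). Of the 3 yolk protein genes, Yp3 fell by 0.46 (SE 0.13), and Yp1 (-0.04) and Yp2 (-0.35) did not pass the test. Without the 3 female 0 mM replicate 1 libraries all 3 passed it, with -0.23 for Yp1, -0.59 for Yp2 and -0.65 for Yp3, so their lack of a call is uncertain. Among 14 photoreceptor genes 13 rose and none fell (median 1.16, adjusted p 3.3e-13, adjusted p = 0.086 with an estimated correlation), and ninaC, a myosin of photoreceptors, rose by 1.15 (SE 0.06). Rises were called for 13 of 15 neuron genes (median 0.79, adjusted p 0.0012, adjusted p = 0.47 with an estimated correlation; median -0.15 under the neural scaling, which these genes help to set), 17 of 21 muscle genes (median 0.65, adjusted p 3.8e-06, adjusted p = 0.19 with an estimated correlation; median -0.34 under the neural scaling, where the call was lost with adjusted p 0.064), 8 of 11 hemocyte genes (median 0.92, adjusted p 0.0025, adjusted p = 0.20 with an estimated correlation; median -0.08 under the neural scaling) and 10 of 12 Malpighian tubule genes (median 1.12, adjusted p 1.5e-08, adjusted p = 0.086 with an estimated correlation). One muscle, 1 hemocyte and 1 tubule gene fell, and all these marker counts were the same adjusted over the list alone. Of 14 fat body genes, which include the 3 yolk protein genes, 4 rose and 2 fell (median 0.06, camera adjusted p 0.21, adjusted p = 0.43 with an estimated correlation). The tubule list shares Uro and Oatp58Dc with the lists above.

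Of 24 neuropeptide and gut hormone genes 19 rose and 2 fell in females (median 0.69, camera adjusted p 0.021, adjusted p = 0.35 with an estimated correlation; median -0.29 under the neural scaling). Of 9 circadian clock genes 8 rose and 1 fell (median 0.89, adjusted p 0.00033, adjusted p = 0.086 with an estimated correlation; median -0.07 under the neural scaling). Both counts were the same adjusted over the list alone. The clock component tim rose by 0.88 (SE 0.07), and to, a clock output gene, by 1.78 (SE 0.10). In all, 17 of 32 lists were called in females, 14 up and 3 down, and camera with an estimated correlation called 0 (7 at an unadjusted p under 0.05, and rotation test fry called 24). When dose labels were exchanged within genotypes, 23 of 100 splits, the real one included, called at least 17 lists. The splits other than the real one called a median of 12. No split balances the doses of a genotype, so each holds part of the auxin effect and these counts are not a chance rate. The number of lists called is thus not taken as evidence by itself of an effect on lists. Counts of members come from the same libraries and stand against 3814 rises and 3818 falls among all 10746 genes tested. Scaling libraries to the neuron and photoreceptor lists, a choice made after the data were seen, moved the median of all genes from -0.01 to -0.99 and left 493 genes higher and 8090 lower. Every female fold change above is relative to the median gene.

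**Figure D3:**
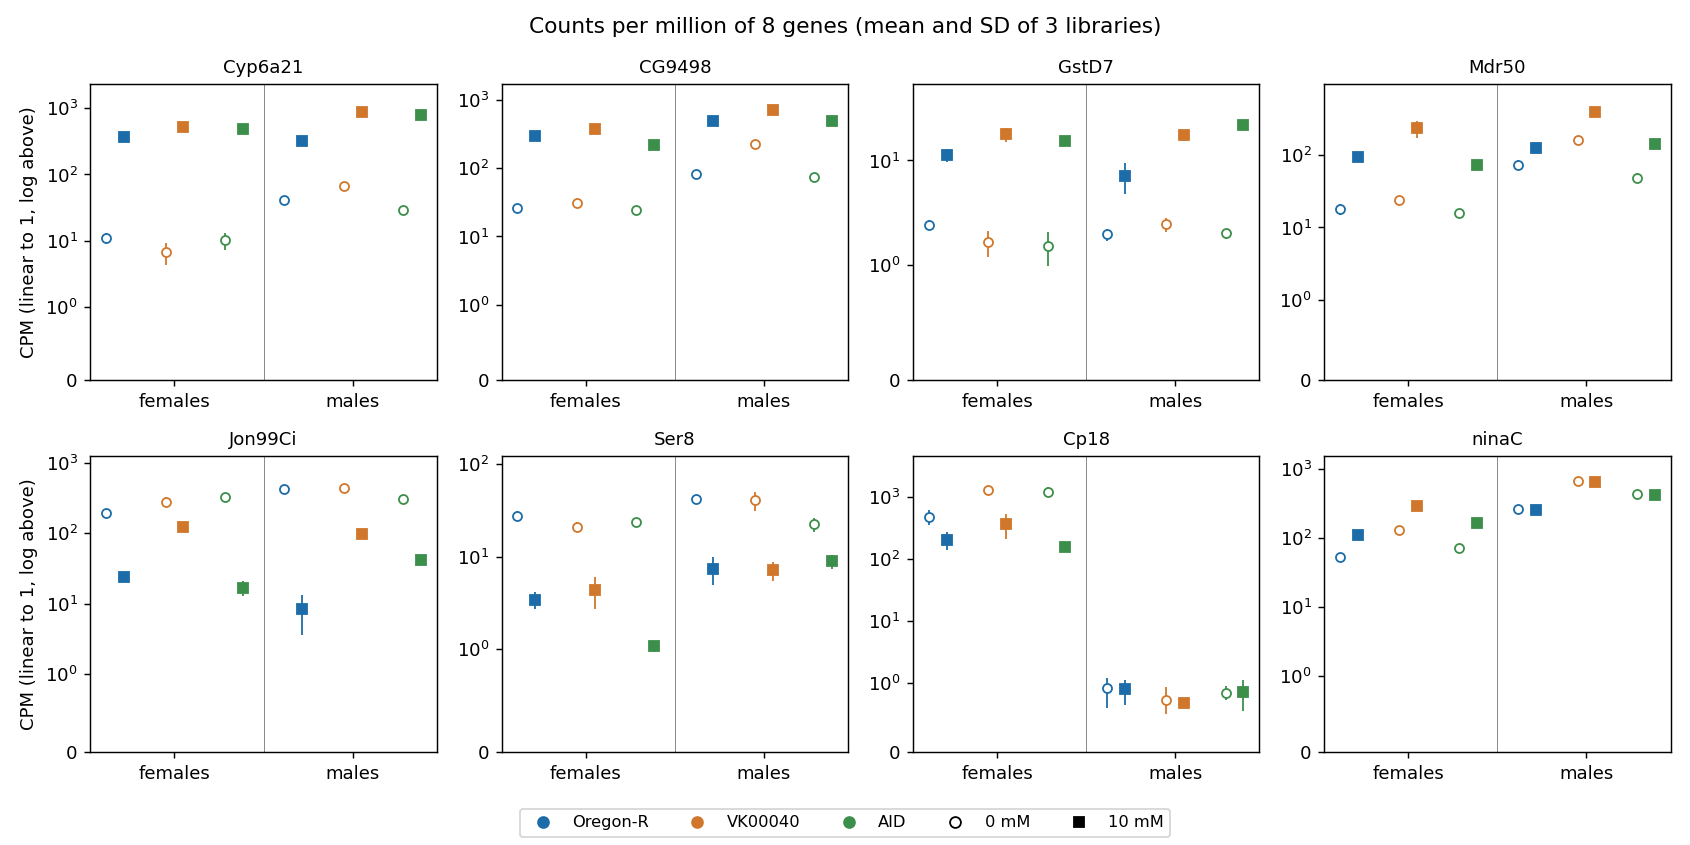
CPM of 8 genes (vertical axis, linear up to 1 and logarithmic above) in each genotype, sex and dose, as mean with SD of 3 libraries; open circles are 0 mM and filled squares 10 mM. Cyp6a21 went from 10.9 to 372 CPM in Oregon-R females and Jon99Ci from 194 to 23.5 CPM, and Cp18 lay under 1 CPM in males.

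In males, auxin changed 3682 of 13630 genes in Oregon-R (1630 higher and 2052 lower), 3563 in VK00040 (1777 and 1786) and 3157 in AID (1770 and 1387), by the same test. In all 3 genotypes 689 genes rose and 531 fell, where independent lists would share 27.6 and 27.4. The mean effect called 5688 genes, 2676 higher and 3012 lower, of which 191 rises and 250 falls were at least 2-fold. Fold changes of pairs of genotypes correlated with r of 0.40 to 0.53 across genes (0.19 to 0.24 with no low-count filter). Scaled to the neuron and photoreceptor lists, 1930 genes rose and 3928 fell, with a shift of the median gene from -0.02 to -0.07. The share of mt:lrRNA rose with auxin in these libraries, as given above.

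Digestive enzyme genes fell in males. Of 47 digestive protease genes 41 fell and 2 rose (median -1.37, camera adjusted p 9.0e-52, adjusted p = 0.0096 with an estimated correlation), and adjusted over the list alone 42 fell and 3 rose. Jon25Biii (FBgn0031653; 2L, 4949941 to 4950767, minus strand) went from 151 ± 27 to 1.46 ± 0.67 CPM in Oregon-R, from 463 ± 68 to 64.5 ± 7.8 CPM in VK00040 and from 243 ± 24 to 41.5 ± 6.7 CPM in AID (SD, n = 3 each). Jon65Ai fell by 4.45 (SE 0.13) and Jon99Ci fell by 3.53 (SE 0.11) on the log2 scale. Of 21 digestive carbohydrase genes 18 fell and 2 rose, also when adjusted over the list alone (median -0.72, adjusted p 1.1e-10, adjusted p = 0.063 with an estimated correlation). This fall was mostly that of Oregon-R, where 18 fell and 1 rose (median -1.97), against 8 falls and 7 rises in VK00040 (median -0.01) and 3 falls and 7 rises in AID (median -0.06). Amyrel, an amylase relative, fell by 3.50 (SE 0.16), and Mal-B1 rose by 1.66 (SE 0.07). In the triglyceride storage and lipolysis list, 19 of 36 genes fell and 6 rose, or 8 adjusted over the list alone (median -0.36, adjusted p 5.8e-06, adjusted p = 0.0096 with an estimated correlation). The predicted lipase genes CG6277 and CG6295 fell by 2.08 (SE 0.09) and 3.85 (SE 0.26; 5.16 without AID male 10 mM replicate 1), while CG1942 (Dgat2) rose by 2.17 (SE 0.11).

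Transcripts of muscle, energy metabolism and ribosomes fell in males by smaller amounts. Of 22 muscle genes 18 fell and 2 rose, also when adjusted over the list alone (median -0.46, camera adjusted p 1.1e-14, adjusted p = 0.012 with an estimated correlation). Mhc, the muscle myosin heavy chain gene, fell by 0.81 (SE 0.04), and Act79B fell by 0.97 (SE 0.04). Of 29 glycolysis and glycogen genes 20 fell and 1 rose, also when adjusted over the list alone (median -0.25, adjusted p 6.2e-08, adjusted p = 0.14 with an estimated correlation). Of 83 oxidative phosphorylation genes 62 fell and 1 rose, with 65 falls adjusted over the list alone (median -0.22, adjusted p 1.2e-10, adjusted p = 0.14 with an estimated correlation). Of 91 cytoplasmic ribosomal protein genes 80 fell and 2 rose, with 82 falls adjusted over the list alone (median -0.20, adjusted p 8.9e-10, adjusted p = 0.25 with an estimated correlation). Over the same libraries mt:lrRNA, chosen after its values were seen, rose by 0.46 (SE 0.06, edgeR adjusted p 6.3e-07). Of 42 accessory gland and ejaculatory duct genes 26 fell and 1 rose, with 29 falls adjusted over the list alone (median -0.39, adjusted p 1.1e-08, adjusted p = 0.15 with an estimated correlation).

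Immune effector genes fell in males, with 26 falls and 5 rises of 44, also when adjusted over the list alone (median -0.50, camera adjusted p 2.3e-05, adjusted p = 0.14 with an estimated correlation). Drsl4 fell by 3.61 (SE 0.17), and PGRP-LB, an amidase that dampens immune signalling, rose by 1.03 (SE 0.05). Of 4 Turandot stress genes 3 fell, also when adjusted over the list alone (median -2.02, adjusted p 0.00047, adjusted p = 0.14 with an estimated correlation). TotA fell by 2.14 (SE 0.21).

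Some detoxification, transport and catabolic genes rose in males as in females. Cyp6a21 rose by 3.82 (SE 0.06), from 28.7 to 67.6 CPM at 0 mM to 321 to 872 CPM at 10 mM over the genotype means, while Cyp6w1 and Cyp6g1 fell by 2.47 (SE 0.06) and 1.59 (SE 0.04). Of 80 P450 genes 19 rose and 33 fell in males (adjusted p 0.50). Of 34 glutathione transferase genes 12 rose, or 13 adjusted over the list alone, and 10 fell (median 0.11, camera adjusted p 0.00034, adjusted p = 0.15 with an estimated correlation). GstD7 rose by 2.73 (SE 0.11) and GstE3 by 1.93 (SE 0.06). Of 14 ABC and organic anion transporter genes 5 rose and 3 fell, with 4 falls adjusted over the list alone (adjusted p 0.00072, adjusted p = 0.080 with an estimated correlation). Their median was 0.00 and turned from above to below 0 with RLE size factors and with the neural scaling. MRP, a multidrug resistance protein gene, rose by 1.32 (SE 0.03) and Mdr50 by 1.20 (SE 0.06). Of 28 amino acid catabolism genes 15 rose and 6 fell, also when adjusted over the list alone (median 0.16, adjusted p 5.2e-06, adjusted p = 0.16 with an estimated correlation), and Uro rose by 2.31 (SE 0.05). Of 12 Malpighian tubule genes 7 rose and 3 fell, also when adjusted over the list alone (median 0.18, adjusted p 1.3e-06, adjusted p = 0.014 with an estimated correlation). Of 9 clock genes 5 rose and 1 fell, also when adjusted over the list alone (median 0.16, adjusted p 0.026, adjusted p = 0.16 with an estimated correlation). CG10182 rose by 5.09 (SE 0.24), CG34217 by 4.58 (SE 0.20), CG13905 by 3.86 (SE 0.11) and CG5550 by 3.52 (SE 0.16). In all, 15 lists were called in males, 5 up and 10 down, and camera with an estimated correlation called 4, those of triglyceride storage and lipolysis, digestive proteases, muscle and Malpighian tubule.

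**Figure D4:**
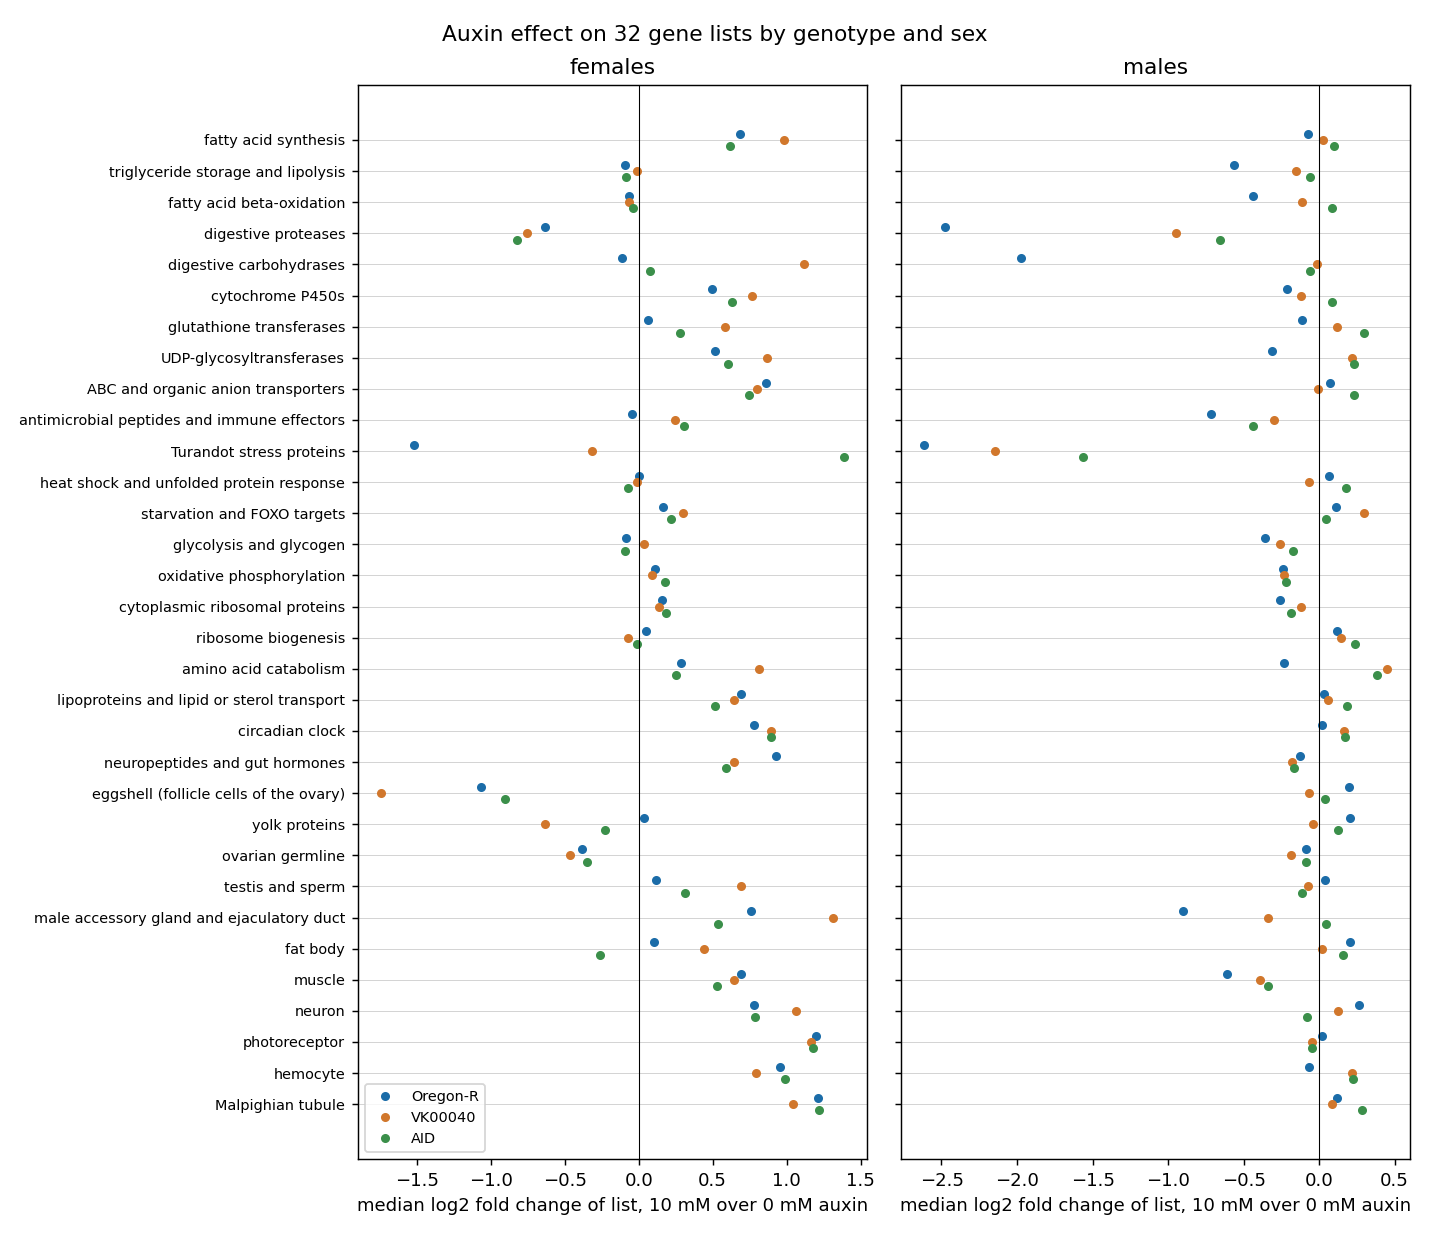
Median log2 fold change of 10 mM over 0 mM auxin (horizontal axis) of each of 32 gene lists in females (left) and males (right), with 1 point per genotype. Over genotypes, the mean effect gave a photoreceptor median of 1.16 in females and a digestive protease median of -1.37 in males; scaled to the neuron and photoreceptor lists, most female medians above 0 turned below 0.

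The second question was whether the response depended on genotype, since the AID line expresses a plant auxin receptor. In females the auxin effect differed among genotypes for 354 of 10746 genes, and AID differed from the mean of the other genotypes for 127 genes, 43 with a higher and 84 with a lower effect. CG6295 had a log2 fold change of -7.68 in AID, -0.80 in Oregon-R and -1.25 in VK00040, a difference of -6.66 (SE 0.58, edgeR adjusted p 5.3e-06). CG17752 fell by 4.42 in Oregon-R and 2.60 in VK00040, with a value of -0.23 in AID (difference 3.28, SE 0.26). CG14406 had values of 0.98, 1.75 and -1.55 in Oregon-R, VK00040 and AID (difference -2.92, SE 0.24). Of 21 digestive carbohydrase genes 1 had a higher and 5 a lower effect in AID, or 2 and 11 adjusted over the list alone (median -0.98, camera adjusted p 5.0e-15, adjusted p = 0.089 with an estimated correlation). This contrast partly reflects the rise in VK00040. By the list medians given above AID was close to Oregon-R, though its mean lay well below its median. The count of 127 genes ranged with single libraries: it was 205 without VK00040 female 0 mM replicate 2, 75 and 82 without AID female 0 mM replicates 2 and 3, and 71, 82 and 82 without AID female 10 mM replicates 1, 2 and 3. It was 290, and that of the genotype difference 550, without the 3 female 0 mM replicate 1 libraries. DESeq2 gave 275 and 632, and 1 fit of all 36 libraries gave 302 and 719.

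In males the effect differed among genotypes for 1994 of 13630 genes. The 4 genes of smallest p with a known enzyme function were the maltase genes Mal-A1, Mal-A6 and Mal-A7 and the amylase gene Amy-d, whose near-identical copy makes its value uncertain. Mal-A1 went from 3307 ± 116 to 639 ± 36 CPM in Oregon-R, from 2597 ± 267 to 3280 ± 10 CPM in VK00040 and from 1711 ± 19 to 2273 ± 153 CPM in AID (SD, n = 3 each, adjusted p 9.3e-16 for the genotype difference). AID differed from the mean of the other genotypes for 1379 genes, 1102 with a higher and 277 with a lower effect. The effect was higher in AID for 32 of 47 digestive protease genes, or 35 adjusted over the list alone (median difference 1.12, camera adjusted p 5.7e-33, adjusted p = 0.026 with an estimated correlation). It was higher for 13 of 21 digestive carbohydrase genes, or 16, with 1 lower, adjusted over the list alone (median 1.11, adjusted p 4.0e-33, adjusted p = 0.00495 with an estimated correlation), and for 23 of 42 accessory gland genes, or 24 adjusted over the list alone (median 0.67, adjusted p 7.8e-19, adjusted p = 0.027 with an estimated correlation). For the carbohydrase genes this difference was mostly the fall in Oregon-R, since the AID median was close to that of VK00040, as given above. CG12057 fell by 7.11 in Oregon-R and 4.55 in VK00040, with a value of -0.62 in AID (difference 5.21, SE 0.27). Uro rose by 3.62 in AID, 1.73 in Oregon-R and 1.58 in VK00040 (difference 1.97, SE 0.11). A single fit of all 36 libraries gave 774 genes for AID and 1128 for the genotype difference.

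The third question was whether females and males responded alike. The mean auxin effect differed between the sexes for 7116 of 13979 genes, with 3755 higher and 3361 lower in females. The photoreceptor and neural genes Gbeta76C, RIC-3 and hig were among the 5 of smallest p, with differences (female minus male) of 1.25, 1.18 and 1.37 on the log2 scale (SE 0.06, 0.06 and 0.07, edgeR adjusted p 1.4e-16, 1.4e-16 and 2.4e-16). Gbeta76C, the beta subunit of the eye G protein, went from 22.2 ± 1.1 to 50.4 ± 3.5 CPM in Oregon-R females and from 124 ± 4 to 119 ± 1 CPM in Oregon-R males (SD, n = 3 each). The female effect was higher for 20 of 22 muscle genes (median difference 0.92, camera adjusted p 4.0e-16, adjusted p = 0.0047 with an estimated correlation), 13 of 14 photoreceptor genes (1.18, adjusted p 6.7e-16, adjusted p = 0.011 with an estimated correlation), 25 of 31 fatty acid synthesis genes (0.71, adjusted p 3.9e-10, adjusted p = 0.043 with an estimated correlation) and 59 of 80 P450 genes (0.78, adjusted p 8.3e-11, adjusted p = 0.043 with an estimated correlation). The counts were the same adjusted over the list alone, except 61 for the P450 genes. Scaled to the neuron and photoreceptor lists, which moved the median of all genes to -0.77, the difference was called for 8248 genes, 611 higher and 7637 lower in females. The list medians were then 0.01 for muscle, -0.16 for fatty acid synthesis and -0.12 for P450 genes. With the preset correlation camera, which compares members with all other genes, still called all 3 lists up (adjusted p 7.9e-05, 0.0071 and 2.1e-05). With an estimated correlation camera called none of the 3 (adjusted p 0.55, 0.67 and 0.55). The direction for fatty acid synthesis and P450 genes thus held only relative to the median gene. Photoreceptor and neuron genes set this scaling, so it says nothing on them. Of 10418 genes tested in both sexes, 1241 rose in both (939 for independent lists) and 686 fell in both (817), while 939 rose in females and fell in males (854) and 719 did the opposite (899). Fold changes of the sexes correlated with r of 0.29 to 0.36 across genes within a genotype, but with 0.095 to 0.12 with no low-count filter and 0.16 to 0.19 in 1 fit of all 36 libraries.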

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

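Of the tests below, those on digestive proteases, the fat body, genes outside the mitochondrial genome, a gene length cause shared by the genotypes and an exchange of dose labels were chosen only after the result was seen, as was the omission of the 3 female 0 mM replicate 1 libraries and the repeat of the genotype contrasts under other settings; the others were planned. The results listed here drew attention because a test of the difference itself called a difference between groups. The auxin effect differed among genotypes for 354 genes in females and 1994 in males, and between AID and the other genotypes for 127 genes and 9 gene lists in females and for 1379 genes and 16 lists in males; with an estimated correlation camera called 0 and 10 of these lists. Between sexes the mean effect differed for 7116 genes and 22 lists, or 5 lists with an estimated correlation.

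In females the genes of smallest adjusted p for a genotype difference were Jon99Ci (1.62e-06), CG14406 (4.48e-06), CG17752 (4.50e-06), bgm (1.70e-05) and CG11594 (1.70e-05). For AID minus the other genotypes the log2 differences were 3.28 for CG17752, -2.92 for CG14406, -2.13 for Jon99Ci, 5.59 for CG42586 and -6.66 for CG6295. In VK00040 females CG42586 had 43 counts over the group at 0 mM and 2 at 10 mM, so the size of its difference is uncertain. In males the genes of smallest adjusted p for a genotype difference were Mal-A1 (9.34e-16), Mal-A6 (9.34e-16), Mal-A7 (1.19e-14), Amy-d (3.02e-14) and CG34040 (5.87e-14). For AID minus the other genotypes the log2 differences were 1.63 for Cyp6d5, 5.21 for CG12057, 2.41 for Cyp6w1, 1.43 for Mal-A1 and 1.97 for Uro. Between the sexes, female minus male, they were 1.25 for Gbeta76C, 1.18 for RIC-3, 1.97 for CG10477, 1.37 for hig and 1.39 for Obp19d.

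In auxin-fed females ovarian transcripts fell while markers of 5 other tissues rose, which a lower share of ovary RNA in the body could produce. The medians of the 5 marker lists ranged from 0.65 to 1.16, and a permutation test of members among lists (n = 73, 10000 permutations) gave a range as large with p = 0.125, so this explanation stays open for these 5 lists. The fat body list without its yolk genes, which the ovary also transcribes, lay lower (median 0.16, quartiles -0.15 and 0.79, n = 11, p = 0.0043 by permutation against the 73 members; all 14 members, tried first, had quartiles of -0.34 and 0.55 and p = 0.00050, which would have excluded it), so a common rise of all other tissues is not shown, and the quartiles are too wide to exclude it. The explanation does not account for digestive proteases, which are not ovarian and had a median of -0.84 with quartiles of -1.87 and -0.14. It was not tested for the other lists that rose in females, from detoxification to neuropeptides. Their medians were 0.31 (glutathione transferases) to 0.89 (clock), and under the neural scaling -0.67 (glutathione transferases) to -0.07 (clock). The explanation thus stays open for these lists too. The 3 female 0 mM replicate 1 libraries do not account for the list calls, since 100% of the lists stayed called in the same direction without them; a smaller ovary and a change of transcription per cell stay open, since neither tissue size nor RNA per fly was measured.

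The female 0 mM replicate 1 libraries stood apart from replicates 2 and 3 in all 3 genotypes, with 2048 genes higher and 2159 lower of 10285. Removing the 18 mitochondrial genes left 4201 genes that differed but shifted the others by a median of only 0.0098 on the log2 scale, so that step decided nothing; a larger mitochondrial share is still not the whole cause, since it moves all other genes of a library by 1 factor, and of these 1956 were higher and 2245 lower (smaller count 1557 to 2041 without single libraries). An exchange of labels between doses is argued against by the positions of these libraries on the auxin axis, at most 0.176, where 10 mM libraries lay at 0.94 to 1.11. Gene length as 1 cause shared by the genotypes is argued against by Spearman rho of opposite sign and far below the 0.3 named in advance, at 0.038 in Oregon-R, 0.095 in VK00040 and -0.13 in AID (-0.14 to 0.16 against single replicates), while a weak length trend within a genotype stays open. The labels give no batch, so a shared day or handling of these libraries stays open, and no biological explanation was tested.

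The auxin effect in AID differed from that in the other genotypes, which the TIR1 transgene might explain. In females this is argued against as a source of an unusual number of differences, since the same contrast made for VK00040 called 300 genes and that for Oregon-R 161, against 127 for AID. VK00040 over AID was 1.73 to 3.61 without single libraries and 1.51 to 2.62 under 7 other settings, so the lowest ratio is close to the limit of 1.5 set for this test, and Oregon-R and AID changed order between settings (190 against 290 without the 3 replicate 1 libraries). In males Oregon-R stood out by 1656 genes, AID by 1379 and VK00040 by 725, so the transgene cannot be told apart from other differences between the 3 stocks, which differ in background throughout. That genes such as CG6295 respond to TIR1 stays open and untested.

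Dose labels were exchanged within each genotype and sex to count how often other splits gave a result as large. For a single genotype there are only 10 splits, too few for a share under 0.05; the real split was the 1 with the most calls each time, with 4779, 5884 and 4723 genes in Oregon-R, VK00040 and AID females against 0 in every other split, and 3682, 3563 and 3157 in males against a highest other value of 0, 0 and 1. Of 100 splits, 1 (the real one) reached the mean effect in females (7632, highest other 6017) and in males (5688, highest other 3906), the shared calls (3335 and 1220, highest other 0) and the sex difference (7116, highest other 6538). The split behind 6017 and 3906 kept 0 of the true 10 mM labels in Oregon-R and VK00040 and 1 in AID. It nearly reversed the doses, so its calls hold the auxin effect itself. For the mean effects the median of the other splits was 0 in both sexes. For the genotype difference, 4 of 100 splits reached 354 in females (highest other 5391) and 4 reached 1994 in males (highest other 2945); for AID, 4 reached 127 (highest other 4255) and 4 reached 1379 (highest other 2161). The 3 other splits kept the dose labels in VK00040 and exchanged them in AID, or the reverse, so their calls hold the auxin effect itself. For gene lists, 23 of 100 splits called at least 17 lists in females (highest other 24) and 6 called at least 15 in males (highest other 17). With 3 libraries per dose in a genotype no split balances the doses, so every split holds part of the auxin effect. These splits therefore cannot tell how many lists chance alone would call, and the number of lists called is not evidence by itself.

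By list, the real camera p was the smallest of all 100 splits for fatty acid synthesis, ABC and organic anion transporters, lipoproteins, clock, muscle, photoreceptor and Malpighian tubule lists in females, and for digestive proteases, ABC and organic anion transporters, muscle and Malpighian tubule lists in males. It was reached by 21 splits for eggshell genes and for amino acid catabolism, 44 for neuron genes and 41 for neuropeptides in females, by 3 to 8 for the other lists called there, and by 16 for accessory gland genes, 14 for amino acid catabolism and 10 for ribosomal proteins in males. Since every split holds part of the auxin effect, these numbers do not give a chance rate for a list.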

How the results depend on the processing

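RLE size factors, both low-count filters and the fits of 6 libraries kept every count of calls within 1.5 times its value, and the cause of the changes below was not tested except where stated. With DESeq2, 632 genes differed among genotypes in females and 275 in AID females; on simulated counts with no genotype difference it called 2 genes falsely for the genotype difference in females and 0 for AID (edgeR 0 and 0), and for the mean effect 11.1% of its calls were false in females and 7.25% in males. One fit of all 36 libraries gave 719 and 302 in females; in males it gave 1128 for the genotype difference, 774 for AID, 1800 for the single effect in AID and 733 shared calls. Without the 3 female 0 mM replicate 1 libraries the female counts were 550 and 290. Camera with an estimated correlation called 0 lists in females and 4 in males, and fry called 24 and 25. Without single libraries the count for AID females ranged from 71 to 205 and that for Oregon-R females against the other genotypes from 96 to 179. The mean effect then ranged from 7327 to 7757 genes in females and from 5364 to 5776 in males.

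Scaled to the neuron and photoreceptor lists, which moved the median of all genes in females from -0.01 to -0.99, these female rises became falls that passed the test: Tps1 (-0.30), CG9140 (-0.56), CG3192 (-0.64), l(3)neo18 (-0.72), RpS5a (-0.44), RpL10Ab (-0.63), RpS14b (-0.72), Nplp2 (-0.27), bol (-0.46), mia (-0.37) and Est-6 (-0.35). Below 0 without passing it were fbp (-0.027), tim (-0.095), sNPF (-0.0098), CG3523 (-0.052), Mlp84B (-0.17), Zasp52 (-0.081) and Gad1 (-0.040). Of the 17 lists called in females 16 stayed called by camera. This test compares members with all other genes, so a shift common to all genes can hardly move its calls. Most female list medians above 0 turned below 0. By camera the muscle list lost its call (adjusted p 0.064), and immune effectors, ribosome biogenesis and fat body gained one (adjusted p 0.0047, 0.0058 and 0.037). Of other named genes, 14 lost and 4 gained a call under this scaling, and 176 stayed called or stayed without a call. Under no other setting did a named gene that was called in the main fit change sign or lose its call. Named genes without a call could change sign, such as Cp7Fa in males (-0.076 to 0.27 without single libraries). Some named genes had no value at an average log2 CPM of at least 2, since the filter removed them.

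A single library moved some large fold changes. CG6295 in males ranged from -5.16 to -3.67, with the lowest value without AID male 10 mM replicate 1, and its AID difference in females from -8.17 to -6.19. CG14219 in females reached 4.20 and the AID difference of CG42586 6.92.

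Correlations between genotypes depended on the genes kept. In females they were 0.32 to 0.39 with no low-count filter and 0.76 to 0.83 at an average log2 CPM of at least 2; in males 0.19 to 0.24 and 0.52 to 0.73. Between the sexes they were 0.095 to 0.12 and 0.34 to 0.42. One fit of all 36 libraries gave 0.42 to 0.48 in females, 0.34 to 0.46 in males and 0.16 to 0.19 between the sexes.

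Replicate numbers did not pair 0 mM with 10 mM libraries. Deviations of 0 mM and 10 mM libraries of the same number correlated at -0.14 to 0.15 in females (3 of 9 pairs over 0.1) and -0.039 to 0.041 in males. Between genotypes, the female 0 mM replicate 1 libraries were related. At 0 mM replicate 1 the correlations were 0.35 to 0.43 (3 of 3 pairs over 0.1). In the other 15 pairs, of both doses, they were -0.18 to 0.33 (7 over 0.1). Of these, the 0 mM pairs lay at 0.056 to 0.33 and the 10 mM pairs at -0.18 to 0.16, so no relation by number was seen at 10 mM. Deviations within a group of 3 are tied, so a shared deviation of replicate 1 also draws replicates 2 and 3 together across genotypes. The 0 mM values of replicates 2 and 3 are therefore not separate evidence of a relation by number. In males the correlations were 0.052 to 0.089 at 0 mM replicate 1 and -0.042 to 0.060 in the other 15 pairs. With a replicate block the mean effect called 7421 genes in females and 5472 in males, the genotype difference 353 and 1742, and AID 147 and 1252; the block moved no count of calls by over 1.5 times.

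With 3 libraries per group, a 1.5-fold change in a single genotype was recovered in 41% to 54% of simulated genes in females, so a gene without a call in a genotype may still respond there.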

Other observations

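Several lists had no call by camera. In females these were triglyceride storage and lipolysis (6 rises and 11 falls of 30), beta-oxidation (9 and 11 of 34), digestive carbohydrases (10 and 8 of 21), immune effectors (15 and 12 of 44), Turandot genes (0 and 0 of 4), heat shock and unfolded protein response (5 and 9 of 27), starvation and FOXO targets (12 and 5 of 26), glycolysis and glycogen (10 and 7 of 26), oxidative phosphorylation (26 and 8 of 67), ribosomal proteins (42 and 3 of 86), ribosome biogenesis (8 and 11 of 32), yolk proteins (0 and 1 of 3), testis (2 and 1 of 4), accessory gland (4 and 0 of 5) and fat body (4 and 2 of 14). The Turandot genes went opposite ways by genotype, with 3 rises in AID (median 1.39) and 2 falls in Oregon-R (median -1.52). AID minus the others had a median of 2.47 (camera adjusted p 6.6e-05, adjusted p = 0.15 with an estimated correlation). In the female 0 mM replicate 1 libraries 3 of the 4 genes were higher than in replicates 2 and 3. Without these libraries the female median of the mean effect turned from -0.25 to 0.29. In males they were fatty acid synthesis (8 and 10 of 30), beta-oxidation (9 and 17 of 33), P450 genes (19 and 33 of 80), UDP-glycosyltransferases (12 and 10 of 33), heat shock and unfolded protein response (8 and 7 of 30), FOXO targets (14 and 8 of 27), ribosome biogenesis (18 and 2 of 32), lipoproteins (8 and 7 of 20), neuropeptides (4 and 14 of 24), eggshell (0 and 0 of 8), yolk (0 and 0 of 3), ovarian germline (3 and 9 of 30), testis (1 and 13 of 33), fat body (5 and 4 of 15), neuron (8 and 2 of 15), photoreceptor (2 and 3 of 14) and hemocyte genes (5 and 2 of 12).

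In the female 0 mM replicate 1 libraries, 12 of 15 neuron genes were higher than in replicates 2 and 3 (median log2 difference 0.61) and 62 of 85 ribosomal protein genes were lower (-0.34). Of 18 genes of the mitochondrial genome 14 were higher (0.92), and 26 of 46 digestive protease genes were lower (-0.43).

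The body color gene y was at 0.16 to 0.40 CPM in Oregon-R females, 2.36 to 4.62 CPM in VK00040 females and 1.30 to 2.66 CPM in AID females. In males it was at 0 to 0.11 CPM in Oregon-R, 1.84 to 8.40 CPM in VK00040 and 2.16 to 2.69 CPM in AID. The lowest values were thus those of the wild-type strain and not those of the yellow white stock VK00040, which was not explained.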
